A study of Mus musculus with 20 samples.

How the data were processed

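Liver RNA of 20 male mice in 4 groups, orchiectomized or sham operated and kept in normoxia or intermittent hypoxia for 2 weeks, is described in the labels, and groups and mouse numbers were taken from the sample titles. The tables held values for 19 of the mice, and Sham_Nx mouse 1 was not analysed here, so Sham_Nx had 4 libraries where 5 had been planned. Per the labels' protocols, total RNA was extracted from frozen liver, messenger RNA was enriched by poly(A) selection, and strand-specific libraries were made with NEBNext directional kits. Per the submitters' processing notes, the reads were handled with bcl2fastq 2.20, fastp 0.23.2, FastQC 0.11.9 and MultiQC 1.12 and quantified with kallisto 0.46.1, and the genome build was GRCm39.

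The authors deposited a table of estimated counts per gene, as kallisto gives them, with 1 column per library. Of its values 27.5% were not whole numbers, so the expected counts were rounded to whole numbers before testing. The authors also deposited a table of normalized expression on a log2 scale with an F-statistic, a score for any difference among groups, and a p-value and q-value per gene. How the authors normalized that deposited log2 table is not given in the sources used here. Its values lay at a median of 0.0727 from log2 reads per kilobase and 1000000 reads computed here with trimmed mean of M-values (TMM) library sizes, over 11344 genes, and 35982 of its genes had an identifier of the counts table. A q-value under 0.05 was given to 1450 genes by the authors. The values are already logarithms, so the pseudocount of 1 intended before the data were seen was not added, and limma-trend was run on the values as deposited.

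The counts table held 36106 genes, of which 11341 were at 0 in every library, and 95 genes that share a symbol with another were named by their identifier. Total estimated counts lay between 29.3 and 69.6 M per library. Technical copies were checked for by a chi-square test between replicate libraries, whose statistic per degree of freedom lay between 20.7 and 198 over all pairs within groups, so no pair agreed within sampling noise and each library was counted once. Fmo genes are given with their neighbours in an annotation of an older build than the authors used, so no coordinates are printed. Kallisto assigns reads by transcript and can split reads between near-identical genes, which applies to the Mup, Cyp2b, Cyp2a, Cyp4a, Sult3a and Serpina1 families.

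The following choices were made before the data were examined: the tests, the comparisons, 32 gene lists, the rule for named genes and the other scalings, filters, tools and models to be tried. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 16164. Libraries were scaled by TMM, and edgeR 4.0.16 fitted its quasi-likelihood model over all 4 groups together in R 4.3.3. The F-test of each contrast gave p-values that were adjusted by the Benjamini-Hochberg (BH) method over all genes, and a gene was called changed at an adjusted p under 0.05. Fold changes are given with a standard error computed from the fold change and its F-statistic. Intervals use that standard error with the normal quantile for the 95% level. They are approximate, and somewhat narrower than the degrees of freedom of the F-test would give. The contrasts were orchiectomy in each exposure, intermittent hypoxia after each operation, both treatments against Sham_Nx, and the interaction. Exact permutation tests of the Fmo genes were two-sided, on log2 CPM with a prior count of 1. The averages of each treatment over both levels of the other were added after the data were seen.

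Gene lists covered flavin-containing monooxygenases, male-biased and female-biased liver genes, hormone signalling, hypoxia-inducible factor targets, oxidative stress, lipid, bile acid, glucose and xenobiotic metabolism, the circadian clock, inflammation, interferon response, respiratory chain, protein folding, cell cycle, hepatocyte zones, and markers of other cell types that liver tissue can hold. Of the 32 lists, 31 could be tested. Of the 5 nuclear RNAs chosen as a sign of RNA quality only Snhg11 was among the genes counted, and it passed the count filter. It fell by 0.85 ± 0.17 (log2 ± SE) after orchiectomy in normoxia (edgeR BH-adjusted p = 0.00342). Fry in limma 3.58.1 tested whether a list's genes move on balance one way, with BH adjustment over 186 tests, the 31 lists in 6 contrasts. Fry does not compare a list with other genes. Camera with a preset correlation of 0.01 and with an estimated correlation were alternatives, and counts "adjusted over the list alone" use BH over the members of a list. Of the 14 fry calls 9 hold in camera with an estimated correlation: the male-biased and female-biased lists after orchiectomy in each exposure and under both treatments, and the flavin-containing monooxygenases in the 3 comparisons where fry called them.

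In each comparison the text draws on flavin-containing monooxygenases, the 8 genes that rose most and the 8 that fell most among genes past the threshold with a mean of at least 1 CPM and no overlap between the compared libraries, leaving out unnamed predicted genes, and up to 4 changed members of each list or, in lists with none, up to 2 members with the smallest p, given as values. From those, genes were described with preference for calls that held without each library in turn. Some genes that met these rules are not reported here. Cyp2d9, Cyp4a12a, Elovl3, Hsd3b5 and Mup20 were fixed as androgen-dependent genes that check the labels.

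The test was tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 63% and 89% for orchiectomy in normoxia (15911 genes), 73% and 85% for intermittent hypoxia in sham mice, and, with the change placed in ORX_IH (15915 genes), 68% and 80% for orchiectomy under intermittent hypoxia, 65% and 79% for intermittent hypoxia after orchiectomy, 65% and 78% for both treatments and 51% and 65% for the interaction. At most 13 unchanged genes were called in a simulation. Simulated genes were drawn independently of each other, with the fitted spread. Sets of genes that are high together in single libraries, such as the muscle genes, were therefore not copied. These rates need not hold for the real libraries.

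The alternatives were another scaling (the size factors of DESeq2, no scaling factors), no filter or a stricter filter on low counts, DESeq2 1.42.0, limma-voom, limma-trend, mouse number as a replicate block, a term for library numbers 17 to 20, the 20 most abundant genes left out, robust dispersion, only the compared groups in the fit, and each library left out in turn. Library numbers 17 to 20 in the labels are 1 mouse of each group, so values within that set could not be compared. Added after the data were seen were fits without ORX_IH 1 and ORX_IH 2, without the 4 libraries highest in skeletal muscle genes, without ORX_Nx 4 and ORX_Nx 5, which were high in acute phase genes, without the 3 libraries highest in pancreatic genes, and with library numbers 1 to 16 only.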

Results

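Liver gene expression was measured by RNA sequencing in male mice that had been orchiectomized, which removes the testes and with them the main source of testosterone, or sham operated. The mice were kept in normal air (normoxia) or exposed to intermittent hypoxia, repeated drops in oxygen that are used to model sleep apnoea, for 2 weeks. The libraries fell into 4 groups: sham operation with normoxia (Sham_Nx, n = 4), sham operation with intermittent hypoxia (Sham_IH, n = 5), orchiectomy with normoxia (ORX_Nx, n = 5) and orchiectomy with intermittent hypoxia (ORX_IH, n = 5). A further Sham_Nx mouse, replicate 1 in the labels, was not analysed here. Each library came from the liver of a different mouse, and libraries are named by group and mouse number. The total estimated count per library lay between 29.3 and 69.6 M, with group means of 58.2, 48.7, 55.0 and 54.5 M in the order given above. At the shallowest library a total of 3 counts, taken as the detection floor, corresponded to 0.102 counts per 1000000 counts (CPM), which covers counting error only. Of 36106 genes, 16164 had enough counts to be tested. The series asks whether low testosterone and intermittent hypoxia act together on the flavin-containing monooxygenases of the liver, enzymes that add oxygen to nitrogen and sulfur atoms of drugs, dietary amines and lipids.

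Androgen-dependent liver genes separated orchiectomized from sham-operated mice in every library. Cyp2d9, a male-biased cytochrome P450, averaged 992 ± 46.9 CPM (SD, n = 4) in Sham_Nx and 145 ± 62.3 CPM (SD, n = 5) in ORX_Nx. Mup20, which encodes the urinary pheromone darcin, averaged 5059 ± 495 CPM (SD, n = 4) and 121.5 ± 73.6 CPM (SD, n = 5) in the same groups. Elovl3, a fatty acid elongase, Cyp4a12a, an arachidonic acid hydroxylase, and Hsd3b5, a steroid dehydrogenase, likewise showed no overlap between orchiectomized and sham-operated livers in either exposure. All 5 genes were lower after orchiectomy under each scaling of the libraries that was tried. The major urinary proteins together took 6.02 ± 0.997% (SD, n = 4) of all counts in Sham_Nx, 4.25 ± 0.903% (SD, n = 5) in Sham_IH, 0.505 ± 0.235% (SD, n = 5) in ORX_Nx and 0.751 ± 0.254% (SD, n = 5) in ORX_IH. The first principal component of log2 CPM held 22.9% of the variance and placed every orchiectomized liver on one side of every sham-operated liver. The second held 12.6% and was highest in ORX_IH 1 and ORX_IH 2, the pair of libraries highest in skeletal muscle genes.

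Fmo2, the flavin-containing monooxygenase that predominates in lung, averaged 23.2 ± 7.62 CPM (SD, n = 4) in Sham_Nx, 37.5 ± 12.2 CPM (SD, n = 5) in Sham_IH, 56.9 ± 23.8 CPM (SD, n = 5) in ORX_Nx and 112 ± 30.1 CPM (SD, n = 5) in ORX_IH. Fmo1 averaged 228 ± 29.9, 247 ± 30.9, 295 ± 67.7 and 348 ± 40.5 CPM (SD) in the same order of groups, and Fmo4 averaged 5.01 ± 0.701, 5.66 ± 0.733, 5.92 ± 1.19 and 7.98 ± 0.787 CPM (SD). Fmo5, the most abundant member in Sham_Nx, averaged 537 ± 71.0, 557 ± 44.0, 411 ± 55.2 and 541 ± 148 CPM (SD). Fmo6 had 25 counts over all libraries, with at most 6 in a library, and Fmo9 had 0 counts, so neither was tested. In the annotation of the older mouse build that was at hand, Fmo4, Fmo1, Fmo2 and Fmo6 follow each other in this order next to Prrc2c, Fmo5 lies between Chd1l and Prkab2, and Fmo9 between Gm4847 and Fam78b. The gene identifiers in the counts table are ENSMUSG00000040181 for Fmo1, ENSMUSG00000040170 for Fmo2, ENSMUSG00000026692 for Fmo4 and ENSMUSG00000028088 for Fmo5. The authors' deposited table, which tests each gene for any difference among groups, lists q = 0.00632 for Fmo2, q = 0.0546 for Fmo4, q = 0.0997 for Fmo1 and q = 0.241 for Fmo5.

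**Figure D1:**
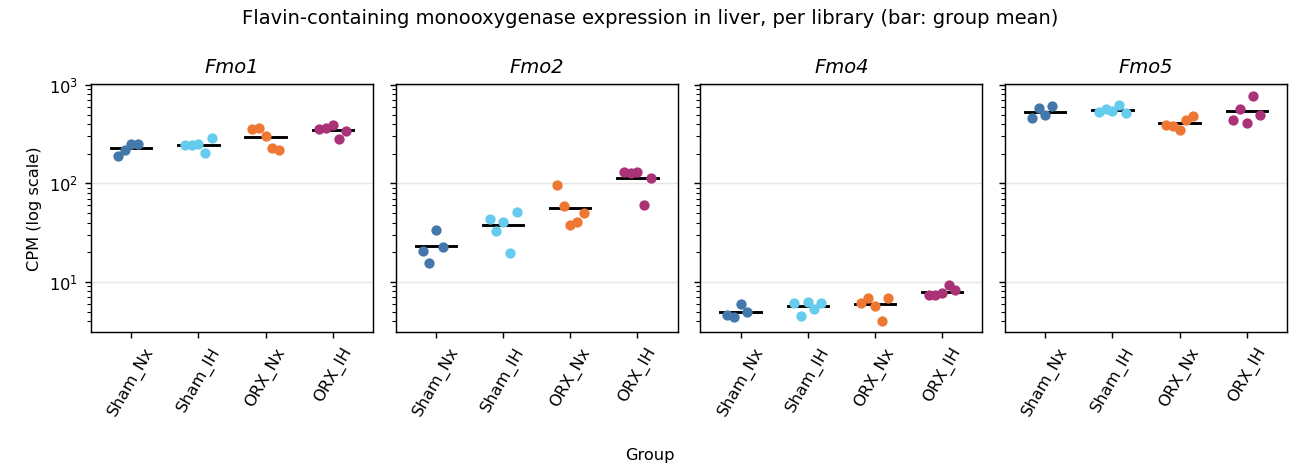
Level of Fmo1, Fmo2, Fmo4 and Fmo5 in each liver library (CPM, log axis) by group, with 1 point per mouse and a bar at the group mean (n = 4 in Sham_Nx, n = 5 in the other groups).

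Orchiectomy in normoxia (ORX_Nx against Sham_Nx, 5 against 4 mice) shifted the liver from a male-biased to a female-biased set of transcripts. Fmo2 rose 2.45-fold, with no overlap between the libraries of the compared groups. The female-biased cytochromes P450 Cyp2b9, Cyp2b13 and Cyp2a4 rose by 8.58 ± 1.05, 9.62 ± 1.03 and 7.48 ± 0.62 (log2 fold change ± SE). The male-biased major urinary protein gene Mup7 fell by 9.35 ± 1.05 on the log2 scale, from 15191 to 23.2 CPM. Across all genes 1274 rose and 1045 fell at an edgeR Benjamini-Hochberg (BH) adjusted p under 0.05, and 693 of these changed at least 2-fold.

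Within the family, orchiectomy in normoxia raised Fmo2 by 1.29 ± 0.31 (log2 ± SE; edgeR BH-adjusted p = 0.0123; exact permutation p = 0.00794). Fmo1 stood at 0.37 ± 0.15, Fmo4 at 0.24 ± 0.15 and Fmo5 at −0.39 ± 0.15, with edgeR BH-adjusted p of 0.0955, 0.287 and 0.0926. When adjusted over the list alone Fmo1 and Fmo2 rose and Fmo5 fell. Fry, which tests whether the genes of a list move on balance in one direction, gave a BH-adjusted p of 0.0525 for the family. The directions were the same under every scaling, but the calls were not the same in every setting. That of Fmo2 ended without the 4 libraries highest in muscle genes and with library numbers 1 to 16 only. Fmo1 passed without ORX_Nx 5 (edgeR BH-adjusted p = 0.046) and Fmo5 without ORX_IH 4 (0.0332).

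Of 25 female-biased genes measured, 21 rose and 4 did not pass (23 rose when adjusted over the list alone), with a median of 3.81 (fry BH-adjusted p = 1.67e-06). Slc22a26, an organic anion transporter, rose by 7.66 ± 0.40, from 0.432 to 87.9 CPM. Hao2, a peroxisomal hydroxyacid oxidase, rose by 7.68 ± 0.91 and Sult3a1, a sulfotransferase, by 6.44 ± 0.84 (log2 ± SE). Outside the lists, the enoyl-CoA isomerase Eci3 rose by 6.31 ± 0.73 and the aldehyde dehydrogenase Aldh3b3 by 5.93 ± 0.61. Of 22 male-biased genes, 19 fell and 3 did not pass (21 fell when adjusted over the list alone), with a median of −3.59 (fry BH-adjusted p = 1.75e-06). Cyp4a12a fell by 6.22 ± 0.56, Hsd3b5 by 6.38 ± 0.66, Mup20 by 5.38 ± 0.48, Elovl3 by 5.15 ± 0.49 and Cyp2d9 by 2.77 ± 0.35 on the log2 scale. Mup1, Mup8, Mup12, Mup14, Mup15, Mup17 and Cyp4a12b lay between −7.26 and −6.57. Reads of the Mup genes, and of Cyp4a12a and Cyp4a12b, can be shared between near-identical copies, so the split among them is uncertain. All of these calls held without each library in turn, and limma-voom ended those of Cyp2b13 and Sult3a1.

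Genes of hormone signalling and lipid handling changed in part. Of 19 androgen and growth hormone signalling genes, 4 rose and 1 fell (6 and 2 when adjusted over the list alone), the median was −0.04 and the mean 0.13, and fry gave a BH-adjusted p of 0.728. Srd5a1, which makes dihydrotestosterone, fell by 1.75 ± 0.22, and the prolactin receptor Prlr rose by 1.01 ± 0.14 (log2 ± SE). In bile acid synthesis and transport, 4 of 17 fell and 1 rose (6 and 1 when adjusted over the list alone; fry BH-adjusted p = 0.197). Cyp8b1, the sterol 12-hydroxylase that sets the share of cholic acid, fell by 1.30 ± 0.29, Cyp27a1 by 0.62 ± 0.12 and the phospholipid exporter Abcb4 by 0.34 ± 0.08. All 24 cholesterol synthesis genes had positive log2 fold changes with a median of 0.54, but 2 passed, also when adjusted over the list alone (fry BH-adjusted p = 0.341). Of 18 fatty acid synthesis genes 4 rose, and of 26 fatty acid oxidation genes 3 fell, in each case the same numbers when adjusted over the list alone (fry BH-adjusted p = 0.48 and 0.186). The oxidation regulator Creb3l3 fell by 0.32 ± 0.08. In glucose metabolism 2 of 19 rose (2 adjusted over the list alone; fry BH-adjusted p = 0.372), with Ppargc1a, a coactivator of gluconeogenesis genes, up by 0.82 ± 0.17. Without the 4 libraries highest in muscle genes the calls of Abcb4 and Creb3l3 ended. Both also ended with no scaling factors, and that of Creb3l3 without ORX_Nx 4 and ORX_Nx 5 and with only the compared groups in the fit.

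Of 25 xenobiotic metabolism genes 6 rose and 3 fell, the same numbers when adjusted over the list alone (fry BH-adjusted p = 0.728), with Cyp2c37 up by 1.46 ± 0.35 and the glutathione transferase Gstt3 up by 1.18 ± 0.23. Of 26 oxidative stress genes 4 rose and 2 fell (9 and 4 when adjusted over the list alone; fry BH-adjusted p = 0.466). The metallothionein Mt2 rose by 3.28 ± 0.80. Of 26 hypoxia-inducible factor targets, 2 rose and 2 fell, also when adjusted over the list alone (fry BH-adjusted p = 0.466). Bhlhe40 rose and the glycolytic regulator Pfkfb3 fell by 0.94 ± 0.22. In the unfolded protein response 8 of 20 fell (11 when adjusted over the list alone; fry BH-adjusted p = 0.125). Of 13 cytosolic heat shock genes 1 fell, or 0 when adjusted over the list alone (fry BH-adjusted p = 0.471). Of 17 circadian clock genes 1 fell, Clock, by 0.36 ± 0.09 (1 adjusted over the list alone; fry BH-adjusted p = 0.95). Of 13 mitochondria-encoded respiratory chain genes 3 fell, with mt-Nd2 down by 0.48 ± 0.11, and of 31 nuclear-encoded ones none passed (3 and 0 when adjusted over the list alone; fry BH-adjusted p = 0.138 and 0.775). Without the 4 libraries highest in muscle genes the calls of Cyp2c37, Gstt3, Mt2, Bhlhe40, Pfkfb3, Clock and mt-Nd2 ended. That of Clock also ended with no scaling factors, those of Cyp2c37, Mt2 and Pfkfb3 with only the compared groups in the fit, those of Cyp2c37 and Mt2 without the 3 libraries highest in pancreatic genes, and that of Mt2 with limma-voom, without ORX_Nx 4 and ORX_Nx 5, and with library numbers 1 to 16 only.

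Inflammatory and immune-cell transcripts were higher after orchiectomy in normoxia. Of 24 acute phase and inflammation genes, 17 rose and 7 did not pass (20 rose when adjusted over the list alone), with a median of 0.98. The fry test gave a BH-adjusted p of 0.0442, and the camera BH-adjusted p = 0.658 with an estimated correlation. The chemokine Cxcl1 rose by 4.92 ± 1.11, the iron-binding Lcn2 by 4.24 ± 0.98, the serum amyloid Saa2 by 3.95 ± 1.00 and the orosomucoid Orm3 by 3.71 ± 0.82 (log2 ± SE). Lymphocyte markers rose on balance, with 3 of 17 up singly (11 when adjusted over the list alone), a median of 1.10 and a fry BH-adjusted p of 0.0442, against a camera BH-adjusted p = 0.662 with an estimated correlation. Gzma, a protease of cytotoxic cells, rose by 2.83 ± 0.62. The levels of the acute phase list were highest in ORX_Nx 4 and ORX_Nx 5, at 1.69 and 1.46 log2 above the mean over libraries, followed by ORX_IH 1 at 0.95, and neutrophil and Kupffer cell markers were also high in ORX_Nx 4 and ORX_Nx 5. The fry call of the acute phase list held only without ORX_Nx 1, ORX_Nx 2, ORX_Nx 3, ORX_IH 1 or ORX_IH 3 (BH-adjusted p between 0.0140 and 0.123 over the 19 fits without 1 library). That of the lymphocyte list held only without ORX_Nx 2, ORX_Nx 3 or ORX_IH 1 (0.00772 to 0.130). Both calls ended without ORX_Nx 4 and ORX_Nx 5, without the 4 libraries highest in muscle genes and with library numbers 1 to 16 only, and that of the acute phase list also without the pair of ORX_IH libraries highest in muscle genes and without the 3 highest in pancreatic genes. The calls of Cxcl1, Lcn2, Saa2, Orm3 and Gzma ended without the 4 libraries highest in muscle genes, and those of the first 4 with limma-voom. Those of Lcn2 and Saa2 ended without ORX_Nx 4 and ORX_Nx 5 and with library numbers 1 to 16 only. That of Saa2 ended with the replicate block, and those of Cxcl1 and Gzma with only the compared groups in the fit.

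Other cell-type markers were counted in the same way, and fry passed for none of these lists. Kupffer cell and macrophage markers had 11 of 13 genes up (12 when adjusted over the list alone), a median of 1.08 and a fry BH-adjusted p of 0.126; the macrophage protein Cd5l rose by 1.41 ± 0.34. In the interferon response 8 of 22 rose (9 adjusted over the list alone), all 22 were positive, and fry gave a BH-adjusted p of 0.165, with the guanylate-binding proteins Gbp3 and Gbp2 up by 1.59 ± 0.36 and 1.38 ± 0.31. Stellate cell and fibroblast markers had 5 of 14 up (6 adjusted over the list alone; fry BH-adjusted p = 0.126), with the collagen gene Col3a1 up by 1.61 ± 0.34. In the cell cycle list 2 of 20 rose (2 adjusted over the list alone; fry BH-adjusted p = 0.219), with the cyclin Ccnd1 up by 1.68 ± 0.32. Cholangiocyte markers had 2 of 10 up, among them Spp1 by 0.53 ± 0.11, neutrophil markers 2 of 6, and sinusoidal endothelial markers 0 of 12 (2, 4 and 0 when adjusted over the list alone; fry BH-adjusted p = 0.236, 0.466 and 0.542). Periportal hepatocyte markers went both ways, with Aldh1b1 up by 1.70 ± 0.26, Ctsc up by 0.79 ± 0.13 and Cyp2f2 down by 0.88 ± 0.19, and 1 of 12 pericentral markers fell (fry BH-adjusted p = 0.33 and 0.857). Of 8 erythroid markers 2 fell, with Alas2, the first enzyme of erythroid haem synthesis, down by 1.61 ± 0.17 and Bpgm by 0.45 ± 0.08 (2 adjusted over the list alone; fry BH-adjusted p = 0.126). Of 8 adipocyte markers 1 fell and of 11 pancreatic acinar markers 0 passed (1 up and 1 down, and 10 down, when adjusted over the list alone; fry BH-adjusted p = 0.857 and 0.536). Without the 4 libraries highest in muscle genes the calls of Cd5l, Gbp3, Gbp2, Col3a1, Ccnd1, Spp1 and Cyp2f2 ended, and that of Cd5l also without ORX_Nx 4 and ORX_Nx 5, without the 3 libraries highest in pancreatic genes, with library numbers 1 to 16 only and with only the compared groups in the fit.

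In this comparison 1995 genes showed no overlap between the libraries of the compared groups, where chance gives 1.59% of genes. Without scaling factors the median log2 fold change of all genes moved to 0.14, and 2362 of 2734 called genes were higher (86.4%, against 54.9% with the main scaling), so the changes given here are relative to the average gene. The count of 2319 genes became 1410 without Sham_Nx 2, 1142 without Sham_Nx 4 and 1370 without Sham_Nx 5. It was 422 without the 4 libraries highest in muscle genes, which include Sham_Nx 2 and Sham_Nx 3, 1475 without ORX_Nx 4 and ORX_Nx 5, 1101 without the 3 libraries highest in pancreatic genes, 918 with only the compared groups in the fit and 1098 with library numbers 1 to 16 only.

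**Figure D2:**
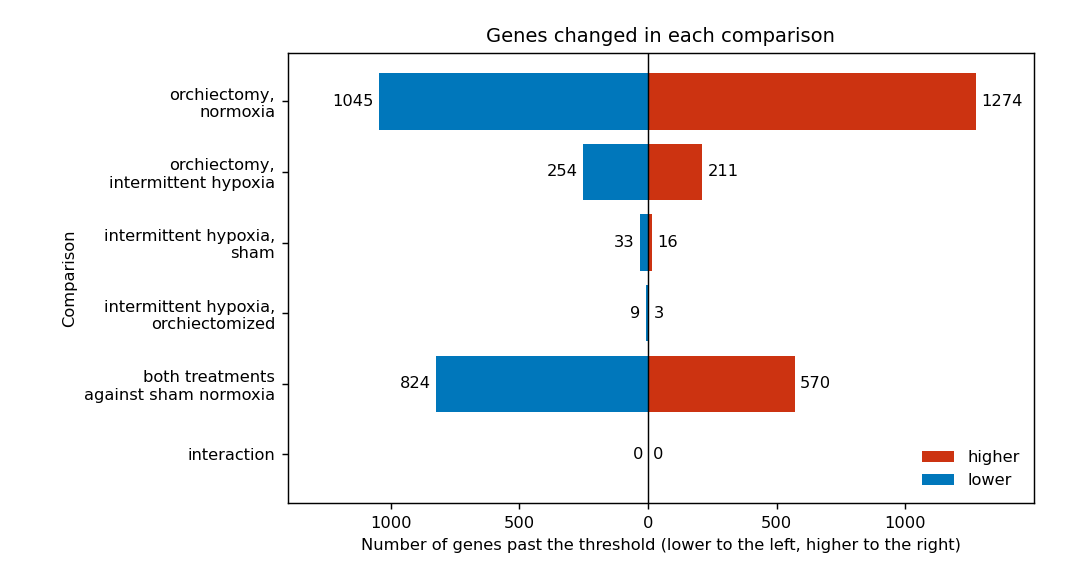
Number of genes with an edgeR BH-adjusted p under 0.05 in each comparison, higher to the right and lower to the left (16164 genes tested, n = 4 in Sham_Nx and n = 5 in the other groups). Orchiectomy in normoxia had 1274 higher and 1045 lower genes, and the interaction had 0.

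Orchiectomy under intermittent hypoxia (ORX_IH against Sham_IH, 5 against 5 mice) also raised female-biased and lowered male-biased transcripts. Fmo2 rose 3.00-fold, with no overlap between the compared groups. Sult3a1 rose by 9.03 ± 0.86, Slc22a26 by 7.39 ± 0.37, Cyp2a4 by 7.04 ± 0.57 and Cyp2b9 by 5.44 ± 0.81 (log2 ± SE), and Mup7 fell by 6.00 ± 0.90 on the log2 scale. In all 211 genes rose and 254 fell at an edgeR BH-adjusted p under 0.05, and 234 of the 465 changed at least 2-fold.

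The flavin-containing monooxygenases rose on balance as a list (fry BH-adjusted p = 0.000829; camera BH-adjusted p = 0.028 with an estimated correlation). Fmo2 rose by 1.58 ± 0.29 (log2 ± SE; edgeR BH-adjusted p = 0.00509; exact permutation p = 0.00794). Fmo1 and Fmo4 each stood at 0.50 ± 0.14, with edgeR BH-adjusted p of 0.0602 and 0.0579, and Fmo5 at −0.04 ± 0.14 (0.917). When adjusted over the list alone Fmo1, Fmo2 and Fmo4 rose. The directions of Fmo1, Fmo2 and Fmo4 were the same under every scaling. The call of Fmo2 ended without ORX_IH 1 and ORX_IH 2, the pair highest in muscle genes, and without the 4 libraries highest in those genes. Fmo1 passed without ORX_Nx 4, without ORX_Nx 5 and without ORX_IH 4 (lowest edgeR BH-adjusted p = 0.0301), and Fmo4 without ORX_Nx 4 and without ORX_Nx 5 (lowest 0.0192). DESeq2, no scaling factors, a fit of only the compared groups and leaving out ORX_Nx 4 and ORX_Nx 5 together each made Fmo1 and Fmo4 pass, as did a stricter count filter for Fmo4.

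Of 25 female-biased genes 18 rose (20 when adjusted over the list alone), with a median of 3.50 (fry BH-adjusted p = 9.39e-07). Of 22 male-biased genes 17 fell (21 when adjusted over the list alone), with a median of −2.74 (fry BH-adjusted p = 1.75e-06). Cyp2b13 rose by 9.45 ± 0.99, Rsph4a, a protein of motile cilia, by 5.20 ± 0.55 and Cyp3a44 by 4.72 ± 0.68 (log2 ± SE). Cyp4a12a fell by 6.02 ± 0.56, Mup12 by 5.68 ± 0.61, Mup20 by 5.23 ± 0.47, Cyp4a12b by 5.09 ± 0.63 and Mup15 by 4.85 ± 0.84, and Mup1 fell by 5.26 ± 0.52. Serpina1e, an antitrypsin paralog, fell by 5.55 ± 0.99, Elovl3 by 4.63 ± 0.48, Hsd3b5 by 3.92 ± 0.56 and Cyp2d9 by 2.18 ± 0.33. These calls held without each library in turn. That of Cyp2b13 ended with limma-voom, that of Mup15 without the 4 libraries highest in muscle genes, and that of Serpina1e without those 4 and without ORX_IH 1 and ORX_IH 2 alone.

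Fry passed for no other list after orchiectomy under intermittent hypoxia. In xenobiotic metabolism 3 of 25 rose and 2 fell (6 and 4 when adjusted over the list alone; fry BH-adjusted p = 0.981), with the glucuronosyltransferase Ugt2b5 down by 0.59 ± 0.10 and the aldehyde oxidase Aox3 down by 1.47 ± 0.26 (log2 ± SE). Lymphocyte markers had 3 of 17 up (7 when adjusted over the list alone; median 0.90; fry BH-adjusted p = 0.108), with the B-cell genes Ms4a1 and Cd79a up by 2.03 ± 0.40 and 1.84 ± 0.31. Lymphocyte and adipocyte markers were highest within this group in ORX_IH 1, the library also highest in muscle genes. Prlr rose by 0.74 ± 0.13, Ccnd1 by 1.68 ± 0.30, and Alas2 fell by 1.78 ± 0.17. Of 24 acute phase genes 1 rose and of 22 interferon response genes 1 rose (6 and 10 when adjusted over the list alone; fry BH-adjusted p = 0.291 and 0.191). Of 13 Kupffer cell markers and of 26 hypoxia-inducible factor targets 0 passed, also when adjusted over the list alone (fry BH-adjusted p = 0.291 and 0.759). In bile acid synthesis and transport 2 of 17 fell (4 when adjusted over the list alone; fry BH-adjusted p = 0.236). The calls of Prlr and Aox3 ended without ORX_IH 1 and ORX_IH 2 and without the 4 libraries highest in muscle genes, and that of Ms4a1 with limma-voom.

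The orchiectomy comparisons in normoxia and in intermittent hypoxia share no libraries, so shared calls do not come from shared mice. The same fit and estimate of each gene's spread served both, so the lists are not independent and the numbers for independent lists are only a guide. Most of the 211 genes higher under intermittent hypoxia were also called higher in normoxia, where independent lists would share 16.6. Of the 254 lower genes 208 were also called lower, against 16.4. In normoxia 169 of the 211 higher genes had the same sign, as did all 254 lower genes. Skeletal muscle genes, high in ORX_IH 1 and ORX_IH 2, had 13 of 17 members among the 211. The median of that list after orchiectomy in normoxia was −4.57. Of the 1274 genes called higher in normoxia 1218 had the same sign under intermittent hypoxia, with a median of 0.85 in normoxia and 0.37 under intermittent hypoxia, and of the 1045 lower genes 999 did, with medians of −0.36 and −0.18. Genes were chosen by their normoxia values, which by itself makes those medians larger. Across all genes, which are not independent replicates, Spearman's rho between the sets of fold changes was 0.551. Under intermittent hypoxia 945 genes showed no overlap between the compared groups, where chance gives 0.794%.

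The count of 465 genes became 272, 264, 258 and 306 without Sham_IH 1, Sham_IH 3, Sham_IH 4 and Sham_IH 5, 704 without ORX_Nx 5, and 224 and 260 without ORX_IH 1 and ORX_IH 2. It was 132 without that ORX_IH pair, 107 without the 4 libraries highest in muscle genes, 158 without the 3 highest in pancreatic genes, 912 without ORX_Nx 4 and ORX_Nx 5, 877 with DESeq2 and 971 without scaling factors, where the median of all genes moved to 0.13 and 85.5% of the called genes were higher, against 45.4%.

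Intermittent hypoxia in sham-operated mice (Sham_IH against Sham_Nx, 5 against 4 mice) changed single genes, while fry passed for none of the lists. Sqle, the squalene epoxidase of cholesterol synthesis, rose 4.45-fold, from 17.1 ± 8.64 (SD, n = 4) to 76.4 ± 17.3 CPM (SD, n = 5). Plin2, which coats lipid droplets, fell by 1.10 ± 0.21 on the log2 scale, and Acot2, a mitochondrial acyl-CoA thioesterase, by 1.55 ± 0.27. In all 16 genes rose and 33 fell at an edgeR BH-adjusted p under 0.05, with 2125 at an unadjusted p under 0.05, and 11 changed at least 2-fold.

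Fmo2 stood at 0.69 ± 0.31 (log2 ± SE; edgeR BH-adjusted p = 0.34), Fmo4 at 0.17 ± 0.15, Fmo1 at 0.11 ± 0.15 and Fmo5 at 0.05 ± 0.15. None of these passed over all genes or when adjusted over the list alone, and fry gave a BH-adjusted p of 0.117 for the family.

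Further genes that rose were Slco1a4, a bile acid and organic anion transporter, by 1.46 ± 0.22, the sphingolipid carrier Apom by 0.63 ± 0.11, the cytochrome P450 Cyp2c70 by 0.85 on the log2 scale, Rdh16f2 by 0.76, Rps4l by 0.74 and Tmem150a by 0.69. Clstn3 fell by 1.52 ± 0.24, the phospholipid transfer protein Pltp by 1.48 ± 0.29, Olig1 by 1.26, Phospho1 by 1.09 and Unc119 by 0.96, and Pparg, a regulator of lipid storage, fell by 0.66 ± 0.11. In cholesterol synthesis 2 of 24 rose, 21 rose when adjusted over the list alone, and 23 had positive fold changes with a median of 1.05 (fry BH-adjusted p = 0.0627; camera BH-adjusted p = 0.241 with an estimated correlation). In fatty acid oxidation 2 of 26 fell, Plin2 and Acot2 (7 when adjusted over the list alone; fry BH-adjusted p = 0.126), and of 8 adipocyte markers 1 fell, Pparg (3 when adjusted over the list alone; fry BH-adjusted p = 0.267). Of 18 fatty acid synthesis genes 0 passed over all genes, while 5 rose and 4 fell when adjusted over the list alone (fry BH-adjusted p = 0.612); Scd1, the stearoyl-CoA desaturase, stood at −2.27 ± 0.51 and Elovl5 at −0.59. Of 20 cell cycle genes and of 22 interferon response genes 0 passed over all genes and 2 each fell when adjusted over the list alone (fry BH-adjusted p = 0.125 and 0.236). Of 26 hypoxia-inducible factor targets 0 passed in either way (median 0.04; fry BH-adjusted p = 0.709); Vegfa stood at 0.27 ± 0.11 and Egln3 at 0.28 ± 0.10. The sex-biased lists held 0 changed genes (2 female-biased genes rose when adjusted over the list alone), with medians of 0.26 for female-biased and −0.10 for male-biased genes (fry BH-adjusted p = 0.536 and 0.775). Cyp4a12a stood at −1.40 ± 0.46, Elovl3 at −0.68, Hsd3b5 at 0.50, Mup20 at 0.18 and Cyp2d9 at 0.06.

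Each of the genes named as changed by intermittent hypoxia in sham mice lost its call without Sham_Nx 2 and without Sham_Nx 5, with adjusted p up to 0.148 over the fits without 1 library (edgeR, BH). Without Sham_Nx 3 those of Sqle, Cyp2c70, Rdh16f2, Rps4l, Tmem150a, Apom, Pltp, Olig1 and Unc119 ended, and without Sham_Nx 4 those of Cyp2c70, Rdh16f2, Apom, Acot2, Olig1, Plin2, Phospho1 and Unc119. Without Sham_IH 1 those of Cyp2c70, Rps4l, Tmem150a, Apom, Acot2, Pltp, Olig1, Plin2, Phospho1, Unc119 and Pparg ended, without Sham_IH 2 those of Rdh16f2, Pltp, Olig1 and Unc119, and without Sham_IH 3 all except those of Slco1a4, Clstn3 and Rps4l. Without Sham_IH 4 those of Cyp2c70, Rdh16f2, Pltp, Plin2 and Phospho1 ended, without Sham_IH 5 those of Cyp2c70, Rdh16f2, Acot2, Pltp, Olig1, Plin2 and Unc119, and without ORX_Nx 1, ORX_Nx 3, ORX_IH 1, ORX_IH 2 or ORX_IH 5 that of Cyp2c70. The count of 49 became 1, 20, 20 and 1 without Sham_Nx 2, 3, 4 and 5, and 13, 26, 9 and 17 without Sham_IH 1, 2, 3 and 5. It was 111, 197 and 82 without ORX_Nx 4, ORX_Nx 5 and ORX_IH 4. It was 117 with a stricter count filter, 419 with DESeq2, 483 with only the compared groups in the fit, 305 without ORX_Nx 4 and ORX_Nx 5, 9 with library numbers 1 to 16 only, 2 without the 4 libraries highest in muscle genes and 0 without the 3 highest in pancreatic genes. Here 1376 genes showed no overlap between the compared groups, where chance gives 1.59%.

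Intermittent hypoxia in orchiectomized mice (ORX_IH against ORX_Nx, 5 against 5 mice) changed few single genes, and the flavin-containing monooxygenases as a list. The median log2 fold change of the list was 0.43 (fry BH-adjusted p = 0.00252; camera BH-adjusted p = 0.028 with an estimated correlation). Cyp39a1, which 7-hydroxylates oxysterols for bile acid synthesis, rose 2.46-fold, from 30.0 ± 10.3 to 73.9 ± 6.23 CPM (SD, n = 5 each). Il1rn, the interleukin 1 receptor antagonist, fell by 1.67 ± 0.31 on the log2 scale and Aldh3b3 by 2.34 ± 0.42. In all 3 genes rose and 9 fell, with edgeR BH-adjusted p of 0.0489 or more, and 2758 genes had an unadjusted p under 0.05.

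Fmo2 stood at 0.98 ± 0.29 (log2 ± SE; edgeR BH-adjusted p = 0.102), Fmo4 at 0.43 ± 0.14 (0.121), Fmo5 at 0.40 ± 0.14 (0.162) and Fmo1 at 0.24 ± 0.14 (0.396). None of these passed over all genes, and Fmo2, Fmo4 and Fmo5 rose when adjusted over the list alone. The list's fry call held without each library in turn (BH-adjusted p from 0.00137 to 0.0105). Fmo2 and Fmo4 passed with DESeq2 (BH-adjusted p = 0.0386 and 0.0459).

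The other 9 changed genes were Adgrl2, up by 0.63 ± 0.12, Ptpn3, up by 0.32 ± 0.05, and Ifi213, Hexa, Zfpm1, Tmem184b, Scpep1, Pik3c3 and Pparg, of which Pparg fell by 0.60 ± 0.11 and the rest lay between −0.81 and −0.31 (log2 ± SE). Cell cycle genes fell on balance, with 0 of 20 past the threshold over all genes and 12 down when adjusted over the list alone, a median of −0.69 and a fry BH-adjusted p of 0.0298, against a camera BH-adjusted p = 0.245 with an estimated correlation. The replication helicase gene Mcm2 stood at −0.74 and the cyclin Ccna2 at −1.19. Oxidative stress genes fell on balance, with 0 of 26 past the threshold and 2 down when adjusted over the list alone, a median of −0.14 and a fry BH-adjusted p of 0.0442, against a camera BH-adjusted p = 0.464 with an estimated correlation. Gsta1, a glutathione transferase, stood at −3.27 ± 0.63. Kupffer cell markers held 0 changed genes, and 10 of 13 fell when adjusted over the list alone, with a median of −0.80 and a fry BH-adjusted p of 0.236. Of 22 interferon response genes 0 passed over all genes and 7 fell when adjusted over the list alone (fry BH-adjusted p = 0.145), with Irf7 at −0.96 and Gbp2 at −1.13. Of 24 acute phase genes 1 fell, Il1rn (5 when adjusted over the list alone; fry BH-adjusted p = 0.423). Kupffer cell and acute phase markers were highest in ORX_Nx 4 and ORX_Nx 5, and neutrophil markers in ORX_Nx 4, on the reference side of this comparison. Of 24 cholesterol synthesis genes and of 26 hypoxia-inducible factor targets 0 passed over all genes (0, and 1 down, when adjusted over the list alone; fry BH-adjusted p = 0.544 and 0.885). Male-biased and female-biased genes held 0 changed genes (5 up and 1 down, and 3 up and 4 down, when adjusted over the list alone; fry BH-adjusted p = 0.418 and 0.938). Hsd3b5 stood at 2.95 ± 0.59, Cux2, a female-biased transcription factor, at 1.52 ± 0.31, Cyp2d9 at 0.66, Mup20 at 0.33, Elovl3 at −0.16 and Cyp4a12a at −1.19. Of 8 adipocyte markers 1 fell, Pparg, while their median was 0.69 and their mean 0.80, and the fry direction was down (BH-adjusted p = 0.885).

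All 12 calls of single genes in this comparison ended without Sham_Nx 5, without Sham_IH 1, 2, 3 or 5, without ORX_Nx 4 and without ORX_IH 2, with adjusted p up to 0.135 (edgeR, BH) over the fits without 1 library. Without ORX_IH 3 all ended except that of Pparg, without Sham_Nx 2 all except that of Scpep1, without Sham_Nx 3 all except those of Adgrl2 and Scpep1, and without ORX_IH 5 all except those of Scpep1 and Pik3c3. Without ORX_Nx 1 those of Cyp39a1, Aldh3b3, Il1rn, Ifi213, Hexa, Tmem184b and Pparg ended, without ORX_IH 1 those of Cyp39a1, Adgrl2, Ifi213, Zfpm1, Pik3c3 and Pparg, and without Sham_IH 4 that of Il1rn. The count of 12 became 0 without each of the first 7 of these libraries, 1, 2 and 30 without Sham_Nx 2, 3 and 4, 212, 232 and 127 without ORX_Nx 2, 3 and 5, and 3, 82 and 3 without ORX_IH 3, 4 and 5. It was 714 with DESeq2, 63 with a stricter count filter and 40 without ORX_Nx 4 and ORX_Nx 5. It was 1 with only the compared groups in the fit, and 0 with limma-trend, with no count filter, with a term for library numbers 17 to 20, with mouse number as a replicate block, and without the ORX_IH pair highest in muscle genes, the 4 libraries highest in them or the 3 highest in pancreatic genes. With the size factors of DESeq2 the called genes were 43.8% higher, against 25.0%. The cell cycle fry call ended without ORX_Nx 4, ORX_IH 2, ORX_IH 3 and ORX_IH 4 (BH-adjusted p from 0.00505 to 0.0767), and that of oxidative stress held only without Sham_Nx 5, Sham_IH 1, ORX_Nx 1 or ORX_IH 5 (0.0183 to 0.116). Both also ended without ORX_Nx 4 and ORX_Nx 5, the ORX_IH pair, the 4 libraries highest in muscle genes and the 3 highest in pancreatic genes.

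The intermittent hypoxia comparisons in sham-operated and in orchiectomized mice share no libraries. They shared 1 higher gene, which was Ptpn3, and 2 lower genes, Pparg and Hexa, where independent lists would share 0.00297 and 0.0184. The same fit and estimate of each gene's spread served both comparisons, so the lists are not independent and those values are only a guide. All 16 genes called higher in sham mice, and 32 of the 33 called lower, had the same sign in orchiectomized mice. Spearman's rho across all genes, which are not independent replicates, was 0.297. In orchiectomized mice 371 genes showed no overlap between the compared groups, where chance gives 0.794%.

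Both treatments together (ORX_IH against Sham_Nx, 5 against 4 mice) raised flavin-containing monooxygenases. Fmo2 rose 4.85-fold, Fmo4 rose 1.59-fold and Fmo1 rose 1.53-fold, each with no overlap between the compared groups, while Fmo5 stood at 1.01-fold. Female-biased genes rose and male-biased genes fell, with Cyp2b13 up by 8.92 ± 1.02 and Cyp4a12a down by 7.42 ± 0.60 (log2 ± SE). In fatty acid oxidation 10 of 26 genes fell and in cholesterol synthesis 7 of 24 rose. In all 570 genes rose and 824 fell at an edgeR BH-adjusted p under 0.05, and 309 changed at least 2-fold.

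Fmo2 rose by 2.28 ± 0.33 (log2 ± SE; edgeR BH-adjusted p = 0.000258), Fmo4 by 0.67 ± 0.15 (0.00764) and Fmo1 by 0.61 ± 0.15 (0.0154), and Fmo5 stood at 0.01 ± 0.15 (0.975). Fmo1, Fmo2 and Fmo4 also rose when adjusted over the list alone. The list rose on balance (fry BH-adjusted p = 3.92e-05; camera BH-adjusted p = 0.0124 with an estimated correlation). Directions were the same under every scaling for these 3 genes. The call of Fmo1 ended without Sham_Nx 2 (edgeR BH-adjusted p = 0.0645), without ORX_IH 1 and ORX_IH 2, and without the 3 libraries highest in pancreatic genes, and those of Fmo1, Fmo2 and Fmo4 ended without the 4 libraries highest in muscle genes.

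Of 25 female-biased genes 18 rose and of 22 male-biased genes 17 fell (20 and 21 when adjusted over the list alone), with medians of 3.42 and −2.57 (fry BH-adjusted p = 1.33e-06 and 1.67e-06). Cyp2b9 rose by 8.55 ± 1.05, Sult3a1 by 8.19 ± 0.87, Slc22a26 by 7.10 ± 0.39, Cyp3a44 by 7.01 ± 0.90, Cyp2a4 by 6.87 ± 0.61 and Hao2 by 4.99 ± 0.89 (log2 ± SE). Mup7 fell by 6.79 ± 0.95, Mup12 by 6.90 ± 0.64, Mup20 by 5.05 ± 0.47, Hsd3b5 by 3.43 ± 0.56 and Cyp2d9 by 2.11 ± 0.34. Mup1 fell by 6.01 ± 0.55 and Elovl3 fell by 5.30 ± 0.50. Fatty acid oxidation fell on balance (16 down and 1 up when adjusted over the list alone; median −0.43; fry BH-adjusted p = 0.0442), against a camera BH-adjusted p = 0.662 with an estimated correlation, and Angptl4, an inhibitor of lipoprotein lipase, fell by 1.43 ± 0.33. In cholesterol synthesis 18 rose when adjusted over the list alone (fry BH-adjusted p = 0.126), with Sqle up by 1.92 ± 0.37. In fatty acid synthesis 6 of 18 rose (8 up and 2 down when adjusted over the list alone; fry BH-adjusted p = 0.418), with the regulator Srebf1 up by 1.98 ± 0.43 and Pnpla3 up by 2.39 ± 0.56. The gluconeogenic Pck1 fell by 1.59 ± 0.38, from 1800 ± 372 (SD, n = 4) to 596 ± 316 CPM (SD, n = 5). Cyp8b1 fell by 1.45 ± 0.29, Abcb4 by 0.49 ± 0.08, Alas2 by 2.31 ± 0.18 and Ugdh, which makes UDP-glucuronate, by 0.56 ± 0.11. Akr1d1, a steroid reductase of bile acid synthesis, rose by 0.95 ± 0.21, Gstt3 by 1.46 ± 0.24 and the acute phase genes Orm2 and Apcs by 3.13 ± 0.74 and 1.26 ± 0.23.

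Other lists held fewer changed genes under both treatments, and fry passed for none of them. In the unfolded protein response 4 of 20 fell (10 down and 1 up when adjusted over the list alone; fry BH-adjusted p = 0.126), and of 24 acute phase genes 6 rose (9 when adjusted over the list alone; fry BH-adjusted p = 0.145). Of 26 oxidative stress genes 5 fell, with a median of −0.08, a mean of 0.18 and a fry direction of down (BH-adjusted p = 0.268). Xenobiotic metabolism had 6 of 25 up and 3 down, bile acid synthesis and transport 1 of 17 up and 3 down, glucose metabolism 1 of 19 up and 2 down, and periportal markers 3 of 12 up and 3 down (fry BH-adjusted p = 0.507, 0.418, 0.887 and 0.448). Of 22 interferon response genes 0 passed in either way (fry BH-adjusted p = 0.938). The fry call of fatty acid oxidation held only without Sham_Nx 3, ORX_Nx 2, ORX_Nx 3, ORX_Nx 5, ORX_IH 3 or ORX_IH 5 (BH-adjusted p from 0.0126 to 0.130), and it ended with the replicate block and without the ORX_IH pair, the 4 libraries highest in muscle genes or the 3 highest in pancreatic genes. The count of 1394 genes became 818 without Sham_Nx 2 and 807 without Sham_Nx 5, and 619, 132 and 504 without the ORX_IH pair highest in muscle genes, the 4 libraries highest in them and the 3 highest in pancreatic genes. Without scaling factors the median of all genes moved to 0.13 and 76.4% of called genes were higher, against 40.9%. Here 2034 genes showed no overlap, where chance gives 1.59%. Outside the female-biased and male-biased lists, the calls named for this comparison that held without the 4 libraries highest in muscle genes were those of Alas2 and Cyp8b1, and that of Cyp2d9 ended there. Those of Angptl4, Pck1 and Orm2 also ended without the ORX_IH pair and without the 3 libraries highest in pancreatic genes, that of Pck1 with library numbers 1 to 16 only, and those of Cyp2b13, Hao2 and Orm2 with limma-voom.

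The interaction term asks whether both treatments together differed from the sum of their separate effects on the log2 scale, over all 19 libraries. For Fmo2 the difference was 0.29 ± 0.42 (log2 ± SE; edgeR BH-adjusted p = 0.928), with an approximate 95% confidence interval from −0.53 to 1.11. For Fmo1, Fmo4 and Fmo5 it was 0.13 ± 0.20, 0.26 ± 0.20 and 0.34 ± 0.21 (edgeR BH-adjusted p = 0.941, 0.833 and 0.805). On the linear scale the joint increment of Fmo2 over Sham_Nx was 89.2 CPM and the separate increments summed to 48.1 CPM, an excess of 41.1 ± 18.4 CPM (SE), and the excesses of Fmo1, Fmo4 and Fmo5 were 34.5 ± 40.7, 1.40 ± 0.798 and 110 ± 81.4 CPM (SE). The interval on the log2 scale includes 0, which leaves open a difference from multiplying effects at least up to its bounds.

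Over all genes edgeR called 0 interactions, with 1025 genes at an unadjusted p under 0.05 and a smallest BH-adjusted p of 0.224. Limma-voom and limma-trend on the authors' values also called 0, and DESeq2 called 68, of which 60 were higher and 16 belonged to the 17 skeletal muscle genes. For 52 of the 68, ORX_IH 1 and ORX_IH 2 were the highest pair of libraries, and DESeq2 called 11 interactions without that pair, 5 of them shared. Among list members named for their small p, values below 0 included the cell-matrix protein gene Spp1 at −0.63 ± 0.15 and Sqle at −1.53 ± 0.48. The male-biased repressor Bcl6 stood at −2.63 ± 0.78 and Cxcl1 at −3.75 ± 1.35. Values above 0 included Bpgm at 0.46 ± 0.11, Plin4 at 1.01 ± 0.30, Cyp2b10 at 1.69 ± 0.72, Pdk4, a kinase that blocks glucose oxidation, at 2.42 ± 0.75 and Hsd3b5 at 2.46 ± 0.78. Of the 31 lists that could be tested 0 passed, and the smallest fry BH-adjusted p was 0.293, for glucose metabolism. For the flavin-containing monooxygenases 0 of 5 passed, also when adjusted over the list alone, the median was 0.26 and the mean 0.00, and fry gave a BH-adjusted p of 0.542. Cholesterol synthesis had 23 of 24 genes below 0 with a median of −0.67 (fry BH-adjusted p = 0.341). The skeletal muscle genes, a list chosen after the data were seen, had a median of 12.9 here, 8.19 after orchiectomy under intermittent hypoxia and 7.21 under intermittent hypoxia after orchiectomy. Their median was 2.64 under both treatments, but −4.57 after orchiectomy in normoxia and −5.78 under intermittent hypoxia in sham mice. They took 1518 CPM in ORX_IH 1, 847 in ORX_IH 2, 231 in Sham_Nx 2, 59.3 in Sham_Nx 3 and 55.5 in ORX_Nx 5, against 10.7 to 24.9 in the others. Pancreatic acinar markers took 1242 CPM in Sham_IH 5, 512 in Sham_Nx 5 and 250 in ORX_IH 1, against 4.40 to 25.1 in the others.

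**Figure D3:**
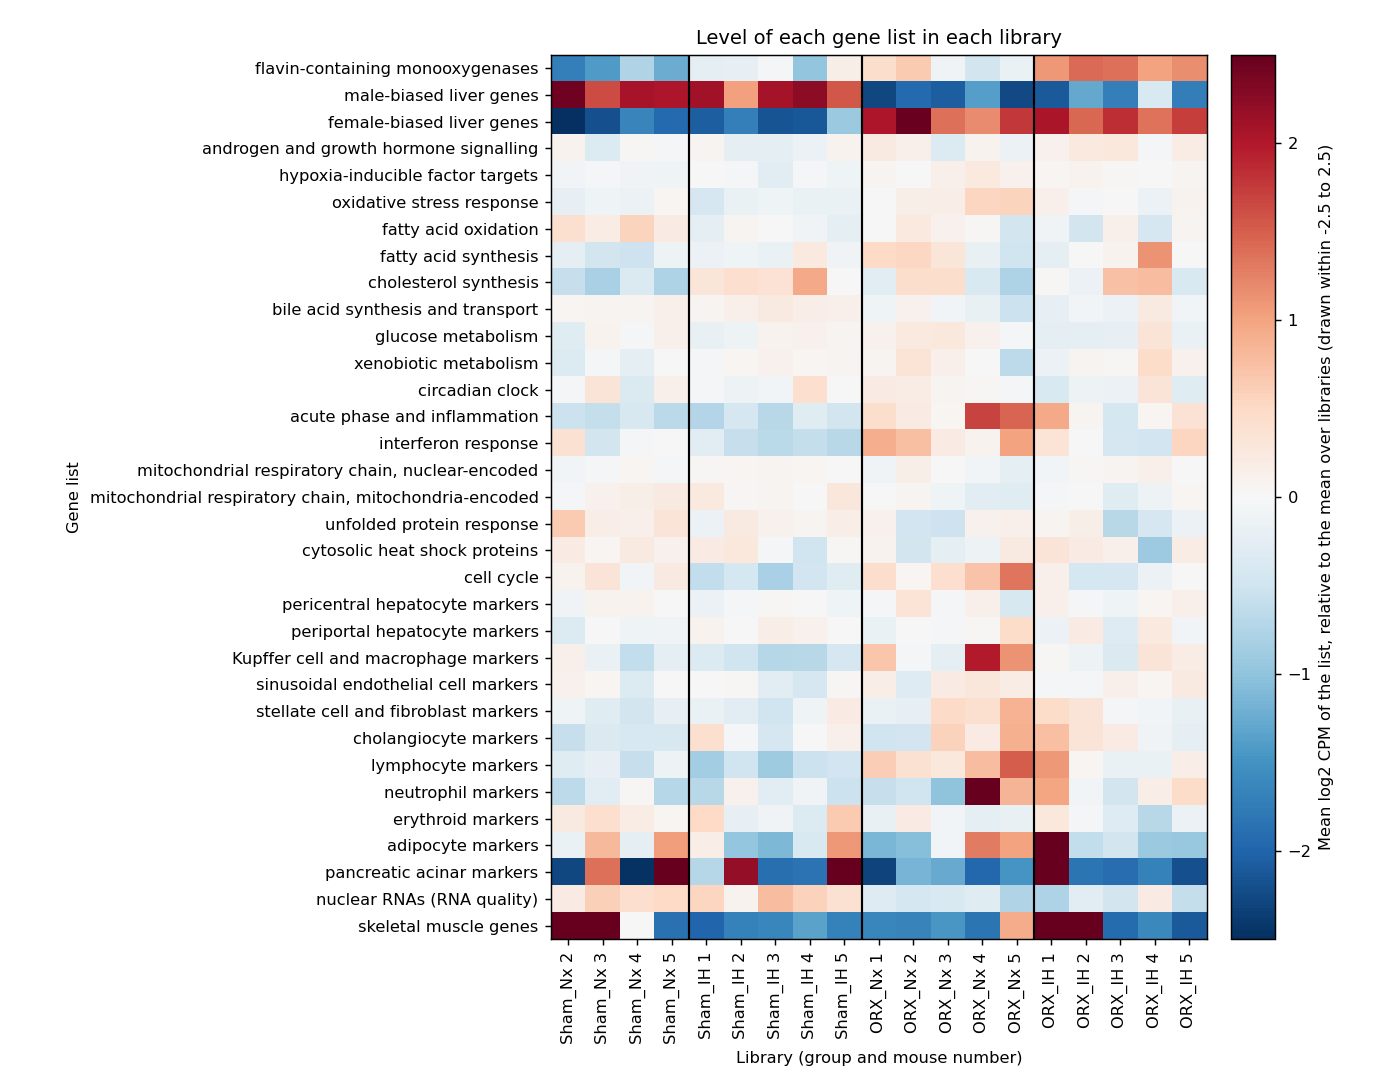
Level of each gene list in each of the 19 libraries, as the mean log2 CPM of its genes relative to the mean over libraries (colour, drawn within −2.5 to 2.5), with lists on the vertical axis and libraries by group and mouse number on the horizontal axis. Male-biased and female-biased genes separate the orchiectomized from the sham-operated libraries, and skeletal muscle genes are highest in ORX_IH 1 and ORX_IH 2.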

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

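The test of whether the 4 libraries highest in muscle genes hold RNA of one kind of muscle, and that of a lower share of hepatocytes, were fixed before their results were seen; all other tests in this part, and the list of skeletal muscle genes, were chosen only after the result was seen. In 16 of 188 groups of values a single library stood apart from the rest of its group, by the gap to its nearest neighbour as a share of the group's range, where chance gives 9.4 at 5 percent. ORX_IH 4 stood apart in 5 of them: low for Fmo2 (0.815) and for cytosolic heat shock proteins (0.843), and high for Cyp4a12a (0.868), glucose metabolism (0.862) and fatty acid synthesis (0.769), whose level was 1.13 log2 above the mean over libraries. ORX_IH 1 was high for lymphocyte (0.730), adipocyte (0.866) and pancreatic acinar markers (0.938). Sham_IH 1 was low for oxidative stress genes (0.853) and high for interferon response genes (0.747), and Sham_IH 4 was high for fatty acid synthesis (0.822) and circadian clock genes (0.776). Sham_IH 2 was low for the share of counts from major urinary proteins (0.745), at 2.70%. ORX_Nx 4 was high for Mup20 (0.724), ORX_Nx 2 low for sinusoidal endothelial markers (0.804) and ORX_Nx 5 high for skeletal muscle genes (0.866).

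Skeletal muscle genes were high in a few libraries, and the fit without the 4 highest called fewer genes. That fit also held fewer mice, so muscle RNA and lost replication cannot be told apart in it. Leaving out Sham_Nx 4 alone, with 18.0 CPM of these genes, also cut the count for orchiectomy in normoxia from 2319 to 1142. Across the 17 genes of the list the lowest Pearson r of log2 CPM between any pair of the 4 highest libraries was 0.163, across genes that are not independent, which argues against RNA of one kind of muscle in all 4; Myh1 and Myh4 stood at 229 and 7.70 CPM in ORX_IH 1, 131 and 7.74 in ORX_IH 2, 21.4 and 20.6 in Sham_Nx 2 and 1.34 and 6.67 in Sham_Nx 3. A joint effect of the treatments as the whole cause is argued against by Sham_Nx 2 and Sham_Nx 3. With neither treatment they held 231 and 59.3 CPM of these genes, while ORX_IH 3, 4 and 5 held 11.5, 17.6 and 10.9. Only 2 of the 5 ORX_IH libraries lay above every library of the other groups. That was known when the pattern was named, so that count does not test it. RNA of skeletal muscle in ORX_IH 1 and ORX_IH 2 stays open: 17 of 17 genes were higher in both than in each of the 15 libraries outside the 4 highest, but the genes were chosen after these libraries were seen to be high in muscle genes, so the count does not test it. The same pair may account for most of the DESeq2 interactions, since it held the highest values for 52 of the 68 called genes.

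Acute phase, lymphocyte and Kupffer cell transcripts were high after orchiectomy in normoxia, most of all in ORX_Nx 4 and ORX_Nx 5. All 3 of the other ORX_Nx libraries lay above the highest Sham_Nx library for the acute phase and lymphocyte lists, so the higher levels were not confined to that pair. The levels were in view when the pair was named, so the count describes them and is no test. Both fry calls also ended without ORX_Nx 4 and ORX_Nx 5. For Kupffer cell markers 1 of the 3 lay above, so whether the pair alone carried that rise stays open. A lower share of hepatocytes, which would raise the markers of all other cell types alike, is argued against as the only cause for the lymphocyte markers. They rose 0.86 log2 more than sinusoidal endothelial markers (two-sided exact permutation p = 0.0159 over 126 splits). No other list was compared in this way. Kupffer cell, cholangiocyte and stellate cell markers had medians of 1.08, 0.57 and 0.31, against 0.16 for endothelial markers, so a lower share as part of the cause stays open. A change in the number or activity of lymphocytes with low testosterone may underlie the rise, but it was not tested, and infection or wounds in single mice stay open as well.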

How the results depend on the processing

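The replicate block, the term for library numbers 17 to 20, the scalings, count filters, DESeq2, limma-voom, limma-trend, robust dispersion, camera and the fits of only the compared groups were planned; the fits without 2, 3 or 4 chosen libraries and with library numbers 1 to 16 only, and the averages over both levels of the other treatment, were chosen after the data were seen. For 256 pairs of a named gene and a comparison, 9189 alternative values were followed, of which 1404 lost the call and 32 gained one. Where the main test or the alternative gave a call, 0 values changed direction. Sign changes of values called in neither are not part of that count. Of 234 called pairs 126 kept the call in every fit without 1 library and 69 in every alternative. Where counts moved, the cause was not tested. The n of 4 in Sham_Nx limits every comparison with that group.

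In the order orchiectomy in normoxia, orchiectomy under intermittent hypoxia, intermittent hypoxia in sham, intermittent hypoxia after orchiectomy and both treatments, the counts of called genes were 2319, 465, 49, 12 and 1394, the interaction 0, and the averages 3549 for orchiectomy and 733 for intermittent hypoxia. Leaving out 1 library gave 1142 to 2662, 224 to 704, 1 to 197, 0 to 232, 807 to 1884, 0 to 0, 2790 to 3797 and 288 to 1005; the 8 Fmo calls went from 7 to 12 and the 14 list calls from 9 to 15. DESeq2 gave 877 for orchiectomy under intermittent hypoxia, 419 and 714 for intermittent hypoxia in sham and after orchiectomy, 68 interactions, 1446 for the hypoxia average and 14 Fmo calls. No scaling factors gave 971 for orchiectomy under intermittent hypoxia. The stricter filter gave 117 and 63 for intermittent hypoxia in sham and after orchiectomy, and no filter 0 for the latter and 472 for the hypoxia average. Limma-trend and the term for library numbers 17 to 20 each gave 0 after orchiectomy. Only the compared groups gave 918 for orchiectomy in normoxia and 483 and 1 for intermittent hypoxia in sham and after orchiectomy. Camera called 75 lists with a preset and 9 with an estimated correlation.

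Without the ORX_IH pair high in muscle genes the counts were 132 for orchiectomy under intermittent hypoxia, 0 for intermittent hypoxia after orchiectomy, 619 for both treatments and 319 for the hypoxia average. Without the 4 libraries highest in them they were 422, 107, 2, 0 and 132 in the order above, 1306 and 8 for the averages, 2 Fmo calls and 9 lists. Without ORX_Nx 4 and 5 they were 1475, 912, 305 and 40 for the first 4 comparisons. Without the 3 libraries highest in pancreatic genes they were 1101, 158, 0, 0 and 504, and 2063 and 157 for the averages. Library numbers 1 to 16 gave 1098 for orchiectomy in normoxia, 9 for intermittent hypoxia in sham and 380 for the hypoxia average. Over 27 pairs of libraries with the same mouse number the correlation of deviations from group means had a median of 0.00369 (−0.197 to 0.395). In 5 pairs it was over 0.1, and 8 of 19 libraries correlated best with their own number. The highest was that of Sham_Nx 5 with Sham_IH 5, both high in pancreatic genes (512 and 1242 CPM). Next came Sham_Nx 2 with ORX_IH 2 (0.251), both high in muscle genes (231 and 847 CPM). Pairing and these shared transcripts cannot be told apart as the source there. The share that chance would give was not computed, so a pairing of some libraries by mouse number is not excluded. With mouse number as a replicate block the counts were 1794, 346, 34, 0 and 1115, with 0 interactions and 15 lists.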

Other observations

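Averaging each treatment over both levels of the other, and all tests in this part, were chosen only after the result was seen. Fry p-values of both averages were adjusted over the 31 lists within each average, not over all contrasts together. For these list calls no camera result and no fit without single libraries is given. They are therefore not comparable with the fry calls of the single comparisons. Averaged over both operations, intermittent hypoxia raised 317 and lowered 416 genes (edgeR, Benjamini-Hochberg (BH) adjusted p under 0.05; 43.2% higher, and 30.7% without scaling factors). Fmo2 rose by 0.84 ± 0.21 (log2 ± SE; edgeR BH-adjusted p = 0.0329), a call that ended without Sham_Nx 2, 3 or 5, Sham_IH 1, 3 or 5, ORX_Nx 4 or ORX_IH 2 (up to 0.0756), and also with the replicate block, with library numbers 1 to 16 only and without each chosen set of libraries (up to 0.366). The flavin-containing monooxygenases were higher on balance, with the smallest fry BH-adjusted p of all lists (0.00115). Of 24 cholesterol synthesis genes 9 rose (median 0.69; fry BH-adjusted p = 0.0402), among them Sqle by 1.39 ± 0.25, Idi1 by 1.15, Msmo1 by 1.11 and Mvk by 1.04. The female-biased repressor Cux2 rose by 1.46 ± 0.23 and the oxysterol hydroxylase Cyp39a1 by 1.07. Of 20 cell cycle genes 6 fell (median −0.52, fry BH-adjusted p = 0.00509), with Ccnb1 down by 2.19 ± 0.37 and Mki67 by 1.41 ± 0.31. Levels of that list were highest in ORX_Nx 5 and ORX_Nx 4, at 1.34 and 0.70 log2 above the mean over libraries, on the reference side. In sham mice alone its median was −0.57. Kupffer cell and lymphocyte markers did not pass, with medians of −0.55 and −0.39 and a fry BH-adjusted p of 0.201 each. Of 22 interferon response genes 5 fell (median −0.65, fry BH-adjusted p = 0.0399), with Rsad2 down by 0.92 and Irf7 by 0.76. Oxidative stress genes fell on balance, with 2 of 26 down singly (median −0.12; fry BH-adjusted p = 0.0128), and Gsta1 by 2.38 ± 0.45. The lipid genes Scd1, Pltp, Acot2, Plin2 and Pparg fell by 1.57, 1.33, 1.10, 0.73 and 0.63 on the log2 scale. Of 26 hypoxia-inducible factor targets 0 passed at 2 weeks (median −0.03; fry BH-adjusted p = 0.845). The count of 733 became 390, 409 and 288 without Sham_Nx 2, 3 and 5, 375, 421 and 389 without Sham_IH 1, 2 and 3, and 388 without ORX_IH 2.

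Averaged over both exposures, orchiectomy raised 1909 and lowered 1640 genes (53.8% higher, and 89.4% without scaling factors, which moved the median of all genes to 0.13). It raised Fmo2 by 1.44, Fmo1 by 0.44 and Fmo4 by 0.37 on the log2 scale, with edgeR BH-adjusted p of 0.000184, 0.00587 and 0.0144, each kept without any 1 library, while Fmo5 stood at −0.21 (0.150). Without the 4 libraries highest in muscle genes the calls of Fmo1 and Fmo4 ended, and that of Fmo4 also with library numbers 1 to 16 only. Beyond the sex-biased lists, fry gave the smallest BH-adjusted p, 0.000127, for the flavin-containing monooxygenases, which were higher on balance. It also found acute phase genes (15 of 24 up), interferon response genes (15 of 22 up), Kupffer cell markers (11 of 13 up), stellate cell markers (6 of 14 up) and lymphocyte markers (12 of 17 up) higher on balance, with BH-adjusted p of 0.0102, 0.0176, 0.0200, 0.0246 and 0.0036. Bile acid genes (7 of 17 down, 1 up), mitochondria-encoded genes (3 of 13 down), unfolded protein response genes (6 of 20 down) and erythroid markers (2 of 8 down) were lower on balance, with fry BH-adjusted p of 0.0214, 0.0155, 0.0222 and 0.0176.

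Other divisions of the same mice were tried for each comparison, 100 each with the real one included. Fewer than 5 of them giving as many genes was the limit set for arguing against chance, without adjustment over the comparisons. Only 1 of the 100, the real one, gave as many genes for orchiectomy in normoxia (2319, highest other 1793), orchiectomy under intermittent hypoxia (465, highest other 1), intermittent hypoxia in sham mice (49, highest other 1), both treatments (1394, highest other 542), the orchiectomy average (3549, highest other 47) and the hypoxia average (733, highest other 3). For intermittent hypoxia after orchiectomy 3 of 100 gave at least the 12 genes of the real division, which is under that limit. However, 11 other divisions gave calls, and the 12 calls ended without any of several single libraries, so chance is not taken as excluded here. Calls in other divisions were not particular to this comparison: 11 gave some for orchiectomy in normoxia and 18 for both treatments. The highest other after orchiectomy gave 249. Like the 1793 and 542 above, that points to a structure of the samples whose source was not tested. For the interaction the real count of 0 means that all 100 had to give as many (highest other 18), so that count says nothing about chance. By genes at an unadjusted p under 0.05 (edgeR), 17 of 100 gave at least the 1025 interactions of the real division (highest other 2142), and chance is not excluded.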
